A study of Mus musculus with 6 samples.

How the data were processed

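Total RNA from untreated NeuNDL-transformed mouse cells was biotin-labelled and measured on 6 arrays, 3 SLK wild-type and 3 SLK knockout. The authors deposited 1 table with a log2 value for each of 41345 probe sets on each array. Per the submitters' processing notes it was made with Affymetrix Expression Console 1.4.1.46. The background correction, the normalization, the summarisation and the annotation are not given in the sources used here, and neither is the base of the logarithm. The highest deposited value, 12.4, exceeds the natural logarithm of a 16-bit scanner's limit (11.1), and log10 values would be lower still, so the values were taken as log2. Array medians (3.93 to 3.97) and quartiles were nearly equal, as after a normalization between arrays, and no further normalization was applied in the main analysis. Values of this kind compress fold changes, above all for dim genes, and no detection calls were used, so a low value does not show that a gene was off. No value was missing, and the most similar pair of arrays, wild-type 2 and 3, differed by an SD of 0.26 over probe sets, with 212 of 41345 values identical, so no array was counted as a repeat of another.

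Probe sets were named through the platform's annotation table: 23521 had 1 gene symbol, 1814 had several and 16010 were not listed there. Of the single-symbol probe sets 23328 matched a gene of the RefSeq annotation of GRCm38.p6 by gene identifier, and no symbol needed updating. The main comparison tested only single-symbol probe sets, and the others were tested apart for the closing section. For the 1082 symbols with more than 1 probe set, the one with the highest mean over all 6 arrays was kept, which gave 22180 genes. Among the genes called, the dimmer probe sets of Adamts8, Angpt1, Cdh1, Dennd2a, Fam107a, Fgf15, Heg1, Lsr, Pstpip2 and Slc35f1 had an unadjusted p above 0.05, while those of Ccdc3 and Deptor did not. The files name no genome build, so no coordinates are given, and GRCm38.p6 was used only for gene names and to group genes by chromosome and neighbourhood.

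Samples were grouped by their titles. Knockout was compared with wild-type with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend, no covariate, all 6 arrays), with Benjamini-Hochberg adjustment and a threshold of 0.05, and no filter on dim genes. Every adjusted p is from this two-sided limma test unless another is named. Standard errors are limma's moderated ones, and log2 fold changes are knockout minus wild-type. Gene lists were tested with camera at its preset inter-gene correlation of 0.01, beside camera with an estimated correlation and fry, each adjusted over the 25 lists. Members were also adjusted over their own list alone. This is less strict than adjustment over all genes, because it does not correct for the other lists. Genes counted as higher or lower only in this way did not pass over all genes. The lists hold 574 genes, of which 529 were measured. The other genes were not analysed here. Some genes stand in more than 1 list. The 25 lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took Slk; the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with no overlap between the groups, leaving out symbols of uncharacterised, olfactory and small RNA genes (2 of the 97 calls bear such symbols); the 3 members of each list with the smallest p; and Erbb2, Sox10 and Stk10. Krt8 and Krt18 were added after their values were seen.

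Replicates 1 to 3 carry the same numbers in both groups, and a fit with a replicate block was made as an alternative. The others were quantile normalization, median centring, leaving out the dimmest 30% or 50% of genes, the mean of a gene's probe sets, every probe set by itself, an intensity trend with and without robust estimation, array weights, and leaving out each array in turn. The fit was tested on simulated arrays with the real genes' means and spreads and 22180 genes: of the genes changed by 0.5, 1 and 1.5 log2 units it recovered 46.3%, 86.6% and 95.5%, and it called 5 of 21961 unchanged genes. A simulated shift of -0.2 in the cholesterol list was called, and none of the other 24 lists was. The simulated genes varied independently of each other, and this shift was larger than the list's real median of -0.07. The simulation therefore says nothing about lists of correlated genes or about shifts as small as the real one. For the closing section, positions of genes were shuffled 10000 times within 20 classes of mean value, and 264 families of symbols with the same letters before the first digit were tested with camera.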

Results

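Gene expression was profiled on 6 one-colour biotin-labelled arrays from mouse mammary tumour-derived cells transformed by NeuNDL, an activated form of the Neu (ErbB2) receptor tyrosine kinase. There were 3 arrays from cells that were wild-type for SLK and 3 from SLK-knockout cells. SLK is a Ste20-like serine/threonine kinase known for its part in cell migration and the turnover of focal adhesions. The series names passages 9, 19 and 29 for its cultures, but the labels tie no passage, clone or line to a sample. The p-values therefore measure the spread between these samples, and the labels do not say whether they are separate cultures or lines. The deposited table held log2 values for 41345 probe sets per array, of which 22180 gene symbols were tested. Array medians lay between 3.93 and 3.97, and the arrays correlated with each other across probe sets with Pearson's r of 0.990 to 0.994. The number of arrays sets the precision of every value.

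The targeted gene was examined first. Slk (probe set 17360181) had a value of 8.28 ± 0.07 (SD, n = 3) in wild-type cells and 7.18 ± 0.03 (SD, n = 3) in knockout cells, and was lower on every knockout array. The log2 fold change was -1.10 (SE 0.06), a 2.15-fold lower signal (limma, adjusted p = 0.0021). The Slk signal stayed above that of 82.5% to 83.1% of all probe sets on the knockout arrays, against 90.5% to 91.5% on the wild-type arrays. Which part of the gene was deleted, and whether the probes lie in it, is not given in the sources used here. The closest relative of Slk, Stk10, had a log2 fold change of -0.12 (SE 0.06, adjusted p = 0.60), and Erbb2, read by the probe set for the mouse gene, one of -0.05 (SE 0.05, adjusted p = 0.78).

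The main comparison asked which genes differed between SLK-knockout and wild-type cells. In knockout cells 72 genes rose and 25 fell, among them higher Sox10, a transcription factor of neural crest and mammary progenitor cells, and lower Krt14, the basal keratin, and Cdh1, which encodes E-cadherin. Of the 97 genes, 18 rose and 2 fell by at least 1 log2 unit, and the changes ranged from 1.28-fold to 3.25-fold. All 97 had knockout arrays wholly above or wholly below the wild-type arrays. Such separation was seen for 16.9% of all genes tested, where chance gives 10%. The counts come from limma with Benjamini-Hochberg adjustment at 0.05, and 2267 genes had an unadjusted p under 0.05. Leaving out any single array left 16 to 28 of the 97 past the threshold, and all 97 kept their sign. Sox10 and Krt14 lost their calls when particular single arrays were left out, and Cdh1 lost its call whichever array it was.

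**Figure D1:**
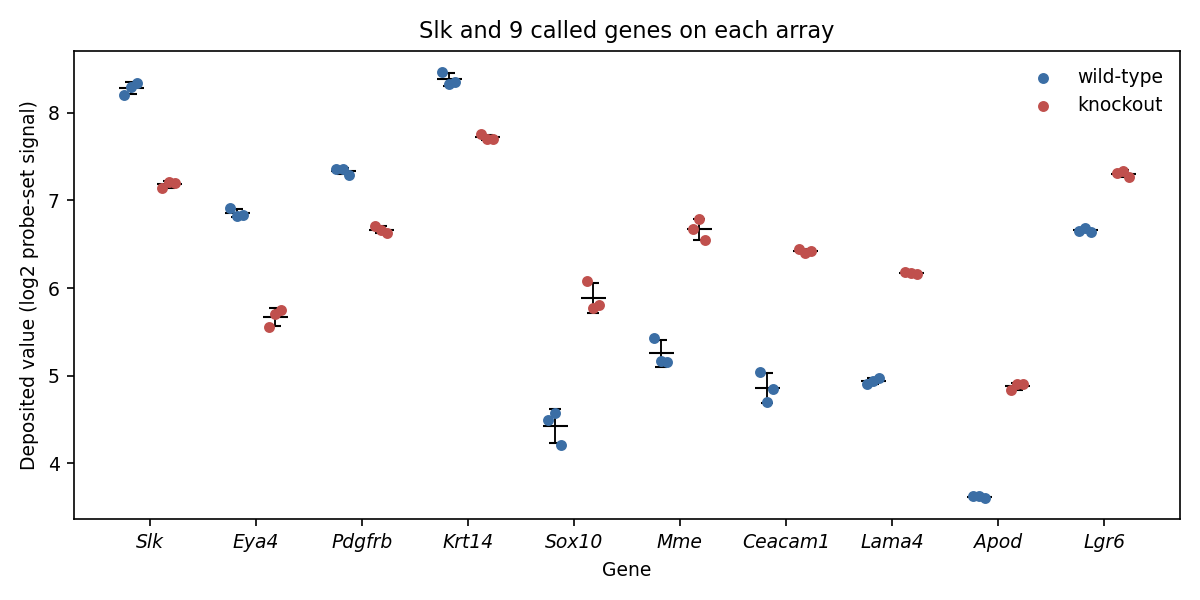
Deposited log2 probe-set signal (y axis) of Slk and 9 other genes past the threshold (x axis) on each of the 3 wild-type and 3 knockout arrays; points are arrays, horizontal bars the group means and whiskers 1 SD. The 2 groups do not overlap for any gene shown: Slk falls from a mean of 8.28 to 7.18, and Sox10 is higher, at 5.89 against 4.42.

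Among the 10 genes that rose most, the highest fold belonged to Slc35f1, a member of a solute carrier family, at 3.25-fold (log2 1.70, SE 0.10, adjusted p = 0.0026). Ceacam1, a cell adhesion molecule, went from 4.86 ± 0.17 to 6.42 ± 0.02 (SD, n = 3 each), a 2.96-fold rise. Sox10 went from 4.42 ± 0.19 to 5.89 ± 0.17 (SD, n = 3 each), or 2.77-fold (adjusted p = 0.0093). Mme, which encodes the surface metalloprotease neprilysin (CD10), rose 2.67-fold (log2 1.42, SE 0.10). Genes of extracellular proteins in this group were Mamdc2 (2.55-fold), Lama4, the laminin alpha 4 chain (2.35-fold), Cnmd, or chondromodulin (2.34-fold), and the lipocalin Apod (2.40-fold). Lama4 and Apod shared the smallest adjusted p of all genes, 0.00082. The remaining genes were Gria3, a glutamate receptor subunit, with 2.43-fold, and Sntb1, a syntrophin, with 2.34-fold. In wild-type cells Slc35f1, Gria3, Apod, Sntb1 and Cnmd were dim, at 2.93 to 3.96 against 4.38 for the median gene. Gria3 was below that level in knockout cells too (4.21). The calls of Sox10, Sntb1 and Cnmd were lost when particular single arrays were left out, with adjusted p up to 0.062, 0.15 and 0.098, while the other 7 were kept whichever array was left out. Averaged over its probe sets, Slc35f1 had a log2 fold change of 0.96, because a second, dim probe set gave 0.22.

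The 10 genes that fell most included Slk itself. Eya4, a transcriptional coactivator and phosphatase, fell furthest, from 6.86 ± 0.05 to 5.67 ± 0.10 (SD, n = 3 each), 2.29-fold (adjusted p = 0.0026). After Slk came Adgrl2, an adhesion G protein-coupled receptor, at 1.87-fold lower, and Mrgpra9, another G protein-coupled receptor, at 1.70-fold lower with a dim signal of 2.97 in wild-type cells. Vtcn1, the immune checkpoint ligand B7-H4, was 1.64-fold lower. Pdgfrb, a platelet-derived growth factor receptor, was 1.59-fold lower (log2 -0.67, SE 0.05, adjusted p = 0.0066). Krt14 went from 8.38 ± 0.07 to 7.72 ± 0.03 (SD, n = 3 each), 1.58-fold lower (adjusted p = 0.0096). Prex2, a Rac exchange factor, was 1.54-fold lower, the angiopoietin gene Angpt1 1.48-fold, and the palmdelphin gene Palmd fell by 0.55 log2 units. Only Eya4 and Slk kept the call whichever array was left out. The highest adjusted p with 1 array left out was 0.050 for Pdgfrb, 0.058 for Prex2, 0.073 for Krt14, 0.091 for Palmd, 0.13 for Adgrl2 and Vtcn1, 0.14 for Angpt1 and 0.17 for Mrgpra9. Averaged over its probe sets, Angpt1 had a log2 fold change of -0.33 and lost the call (adjusted p = 0.096).

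The lists of mammary cell identity addressed whether the cells moved along the luminal, basal or stem-like axis. They were fixed with the knowledge that a basal or stem-like state had been reported after loss of SLK in such tumours, so they are not independent evidence of a direction. In the luminal list 1 of 26 measured genes fell, Cdh1 (1.34-fold lower, adjusted p = 0.022), and none rose. Adjusted over the list alone 5 were lower, with Epcam at log2 -0.35 (SE 0.06) and Rab25 at -0.50 (SE 0.08) beside Cdh1. Epcam and Rab25 had adjusted p of 0.083 and 0.088 over all genes. The keratins Krt8 and Krt18, added after their values were seen, had log2 fold changes of 0.15 and 0.14 and passed neither test. In the basal and myoepithelial list 1 of 25 rose and 2 fell: Mme was higher, Krt14 and Id4, an inhibitor of helix-loop-helix factors, were lower (Id4 1.36-fold, adjusted p = 0.038). The counts were 3 higher and 5 lower adjusted over the list alone. In the stem-cell-associated list 3 of 24 rose, namely Sox10, the R-spondin receptor gene Lgr6 (1.57-fold, adjusted p = 0.0066) and Notch4 (1.36-fold, adjusted p = 0.049), and none fell. Of that list 3 rose and 2 fell adjusted over the list alone. As wholes, none of the 3 lists stood apart from the rest of the array: camera gave adjusted p = 0.44 for luminal, 0.20 for basal and 0.96 for stem-cell-associated genes. The medians of the luminal and stem lists (0.02 and -0.02) had the opposite sign to their tests, which followed the means (-0.04 and 0.07). In the milk protein list 1 of 11 rose, Csn3 (kappa-casein, 1.86-fold, adjusted p = 0.029), which was dim at 2.99 in wild-type cells, and the list gave camera adjusted p = 0.90. Csn3 was again the only call, 1 higher, adjusted over the list alone, and the list's median (-0.02) differed in sign from its mean (0.06) and its test. Btn1a1 and Csn1s1, the next members of that list, had log2 fold changes of -0.15 and 0.11. With 1 array left out Lgr6 reached an adjusted p of 0.061 at most, while Cdh1, Id4, Notch4 and Csn3 lost the call whichever array it was. For Cdh1 the mean of its probe sets lost it too (log2 -0.27, adjusted p = 0.45). Notch4 had adjusted p = 0.053 with means of probe sets and also lost the call with quantile normalization.

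**Figure D2:**
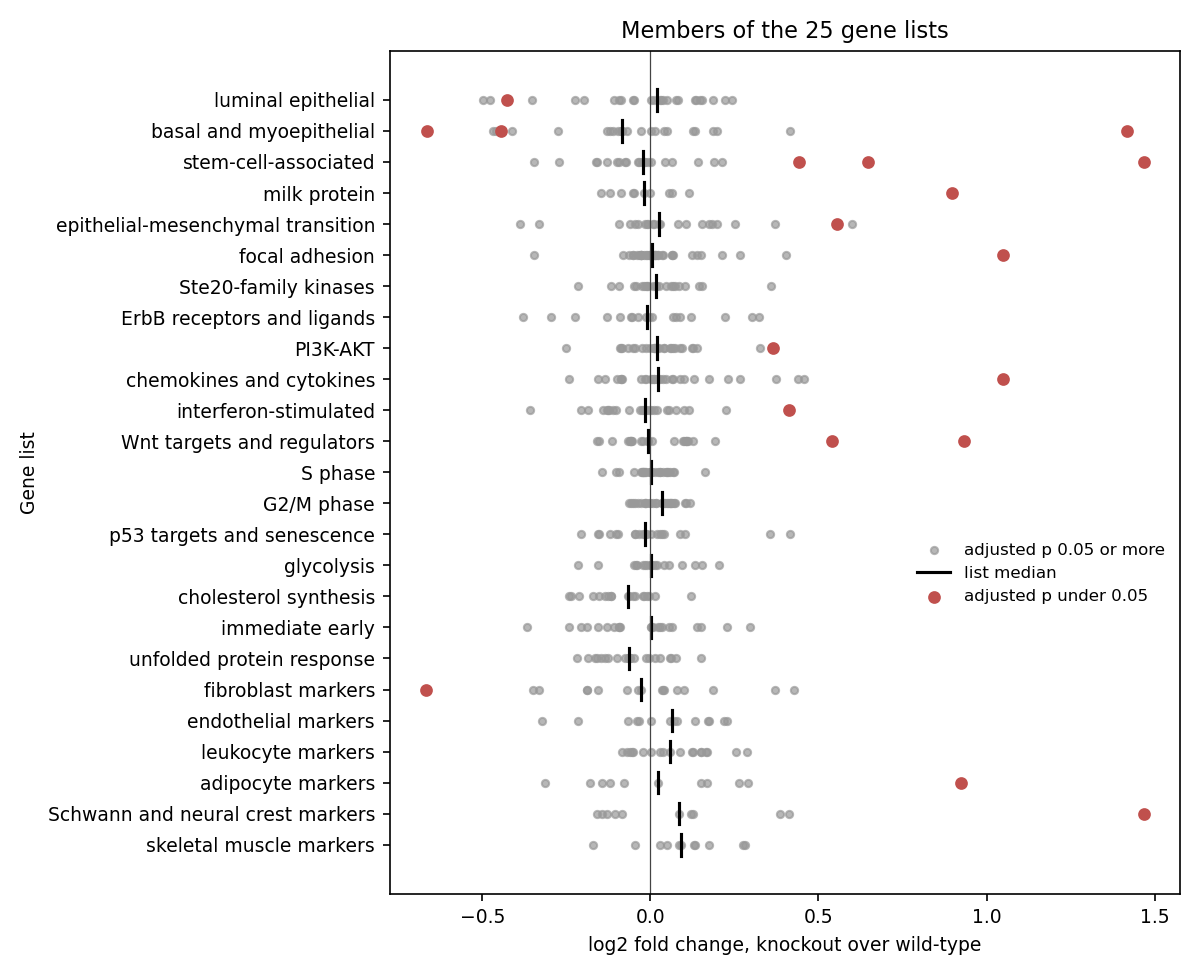
Log2 fold change of knockout over wild-type (x axis) for the measured members of each of the 25 gene lists (y axis); each point is a gene, red where the adjusted p over all genes is under 0.05, and black bars are list medians. The red points are few and go both ways in the basal list, and the cholesterol synthesis members lie mostly left of 0, with a median of -0.07.

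SLK's known link to adhesion and migration made the focal adhesion and epithelial-mesenchymal lists of interest. In the focal adhesion list 1 of 37 measured genes rose, Parvb (beta-parvin, an integrin-linked adaptor), from 6.30 ± 0.09 to 7.34 ± 0.08 (SD, n = 3 each; 2.07-fold, adjusted p = 0.0042), and none fell. This became 3 higher adjusted over the list alone, the others being Tns1 (log2 0.40, SE 0.07) and Src (0.27, SE 0.05). Over all genes Tns1 and Src had adjusted p of 0.11 and 0.13. The list as a whole gave camera adjusted p = 0.39. In the epithelial-mesenchymal transition list 1 of 23 rose, Tgfbi (1.47-fold, adjusted p = 0.038), with Mmp9 at log2 0.60 (adjusted p = 0.054) and Mmp14 at -0.33 (adjusted p = 0.097). Adjusted over the list alone, 7 rose and 1 fell, and camera gave adjusted p = 0.093. None of the 23 Ste20-family kinases passed the threshold, over all genes or adjusted over the list alone. Their smallest p belonged to the dim gene Nrk (log2 0.36, adjusted p = 0.29), then Stk26 (-0.22) and Stk24 (-0.09), and camera gave adjusted p = 0.77. Parvb kept its call whichever array was left out, and Tgfbi lost it each time (adjusted p up to 0.16) and with median centring (0.056).

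The signalling lists held few calls, and none passed camera as a whole in the main analysis. Among 31 chemokines and cytokines Ccl9 rose, from 7.28 ± 0.05 to 8.33 ± 0.09 (SD, n = 3 each; 2.07-fold, adjusted p = 0.0030), and none fell. The count was 4 higher adjusted over the list alone, with Ccl2 at log2 0.37 (SE 0.06) and Cxcl14 at 0.46 (SE 0.07), and camera gave adjusted p = 0.16. Ccl2 and Cxcl14 each had adjusted p = 0.077 over all genes. Among 25 Wnt targets and regulators 2 rose, both antagonists of the pathway: Nkd2 (1.91-fold, adjusted p = 0.022) and Sfrp1 (1.45-fold, adjusted p = 0.026). The same 2 were found adjusted over the list alone, Dkk1 had a log2 fold change of 0.19, and camera gave adjusted p = 0.44, with a median (-0.01) of the opposite sign to the mean (0.07) and the test. In the PI3K-AKT list 1 of 29 rose, the mTOR inhibitor gene Deptor (1.29-fold, adjusted p = 0.041). Adjusted over that list alone 2 were higher, Deptor and Inpp4b (log2 0.33), and 1 was lower, Pik3r1 (-0.25), with camera adjusted p = 0.43. Inpp4b and Pik3r1 had adjusted p of 0.11 and 0.12 over all genes. None of the 18 ErbB receptors and ligands passed over all genes. Adjusted over the list alone 2 were higher and 2 lower, among them Egfr (log2 -0.38, SE 0.05), Ereg (0.32, SE 0.07) and Epgn (-0.30, SE 0.07), with camera adjusted p = 0.83. Egfr, Ereg and Epgn had adjusted p of 0.055, 0.16 and 0.18 over all genes. Of 26 interferon-stimulated genes 1 rose, Oas3 (1.33-fold, adjusted p = 0.045), also when adjusted over the list alone. Irf9 and Tap1 had log2 fold changes of -0.21 and -0.13, and camera gave adjusted p = 0.43. Of these calls only that of Ccl9 was kept whichever array was left out. The highest adjusted p was then 0.11 for Nkd2, 0.13 for Sfrp1, 0.19 for Deptor and 0.18 for Oas3. Deptor also lost its call with the mean of its probe sets (adjusted p = 0.084), and Oas3 with median centring (0.059).

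Genes of cholesterol synthesis were the only one of the 25 lists past the camera threshold, with adjusted p = 0.0034 at the preset correlation. That call was lost with adjusted p = 0.55 with an estimated correlation and with fry (adjusted p = 0.092). Of 19 measured members 17 had a lower mean in knockout cells, with a median log2 fold change of -0.07. Lss (lanosterol synthase) had -0.24 (SE 0.07), Fdps (farnesyl diphosphate synthase) -0.24 (SE 0.07) and Insig1 -0.17 (SE 0.05). No member passed the threshold by itself, over all genes or adjusted over the list alone. On wild-type arrays 1 to 3 and then knockout arrays 1 to 3, the median deviation of the list's members from their gene means was 0.08, 0.04, 0.02, -0.03, -0.04 and -0.07. That of the small nucleolar RNA genes named Snord, whose share depends on RNA preparation among other things, was 0.16, 0.09, 0.03, 0.01, -0.13 and -0.15, so that both had the same descending order over all 6 arrays. Because both sets were lower in knockout cells, their shared order between the genotypes was given in advance. Only the order within each genotype was free to differ. Within each genotype both sets fell from replicate 1 to replicate 3. Effects of RNA preparation and of passage were not tested, and the labels tie no passage to an array. The unfolded protein response list had 17 of 23 members lower, with no member past either threshold and camera adjusted p = 0.069. Its leading members were the chaperone genes Dnajc3 (log2 -0.22) and Calr (-0.16) and Edem1 (-0.13).

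Proliferation and metabolic lists held no call over all genes. None of 27 S phase genes (Rrm2 0.16, Rrm1 -0.10 and Chaf1b -0.09 on the log2 scale) and none of 29 G2/M genes (Kif2c 0.12, Aurka 0.10, Cdc25c 0.11) passed either threshold, with camera adjusted p of 0.96 and 0.43. The 23 p53 targets and senescence genes gave camera adjusted p = 0.69, with a test and a median (-0.01) below 0 and a mean just above it (0.0021). Of them 2 were higher adjusted over the list alone, the cell cycle inhibitors Cdkn2b (log2 0.41, SE 0.06) and Cdkn2a (0.36, SE 0.06), and Ei24 had -0.15. Over all genes Cdkn2b and Cdkn2a had adjusted p of 0.058 and 0.097. The 19 glycolysis genes (Pfkm 0.15, Ldhb -0.22, Slc2a1 0.13) gave camera adjusted p = 0.90. The 22 immediate early genes, which respond to handling (Jun 0.30, Egr2 -0.24, Dusp1 0.23), gave 0.43, with a test and a mean (-0.03) below 0 and a median just above it (0.0021), and neither list had a member past either threshold.

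Markers of other cell types that a tumour culture could hold were compared in the same way. Of 17 fibroblast markers Pdgfrb fell, while Dcn and Postn had log2 fold changes of 0.43 and 0.37, and 2 rose and 4 fell adjusted over the list alone. Among 11 adipocyte markers Fabp4 rose, 1.90-fold (adjusted p = 0.029, and up to 0.14 with 1 array left out), with Cidec at -0.31 and Car3 at 0.29, and 1 rose and 1 fell adjusted over the list alone. Among 11 Schwann and neural crest markers Sox10 rose, with Tfap2b at 0.41 and Tfap2a at -0.16, and 2 rose adjusted over the list alone. None of 14 endothelial (Robo4 0.23, Sox17 0.22, Tek -0.22), 19 leukocyte (Tyrobp 0.29, Fcer1g 0.26, Cd14 0.17) and 11 skeletal muscle markers (Myh1 0.27, Myod1 0.13, Myog 0.28) passed over all genes. Adjusted over the list alone, 2 endothelial markers rose, and no leukocyte or muscle marker passed. Camera adjusted p was 0.45 for fibroblast, 0.23 for muscle and 0.43 for endothelial, leukocyte, adipocyte and Schwann markers. Of the 47 Snord genes none passed the threshold. Their median log2 fold change was -0.19, with 3 of 47 having a higher mean in knockout cells (camera adjusted p = 5.7e-11 over 264 symbol families, adjusted p = 0.98 with an estimated correlation).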

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

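No result for a gene named by the rule changed sign under the alternatives, in which Krt8 and Krt18 were not followed. The Slk change (log2 -1.14 to -1.07) stayed past the threshold in all 16, with adjusted p from 3.1e-07 to 0.046. The number of genes called did depend on the setting, and the cause was not tested beyond what follows. From 72 higher and 25 lower genes, the counts went to 143 and 63 without the dimmest 30% of genes, to 202 and 139 without the dimmest 50%, to 265 and 176 with an intensity trend and to 264 and 179 with a robust fit and trend, which kept 95 of the 97 genes. They went to 25 and 4 when each of the 41345 probe sets was tested by itself, and to 5 and 1 with the replicate block. The deviations of same-numbered arrays from their group means correlated at 0.0437, 0.0168 and -0.0656, and 2 of 6 arrays correlated best with their own number, so the shared numbers were not taken to pair the samples. The block kept 5 of the 32 named calls other than Slk (Slc35f1, Ceacam1, Mamdc2, Apod and Lama4) and the call of the cholesterol list (adjusted p = 0.0078). Those of Mme, Gria3, Eya4, Parvb and Ccl9, kept whichever array was left out, were lost with the block (adjusted p from 0.064 to 0.090). Leaving out 1 array gave 13 to 24 higher and 2 to 5 lower genes, the lowest total, 16, without wild-type replicate 3. Each of these fits tests fewer samples. Higher genes made up 74.2% of the calls, 76.5% after quantile normalization and 73.6% after median centring, but 59.2% without the dimmest 50% of genes, 60.1% with an intensity trend, 59.6% with the robust fit and trend, 86.2% with every probe set, and 81.2% to 92.3% with 1 array left out. The number of lists past the threshold went from 0 higher and 1 lower to 3 higher without the dimmest 50% of genes, to 1 higher and 2 lower with an intensity trend and with the robust fit and trend alike, and to 0 lower with an estimated correlation or fry. It ranged from 0 to 1 higher and from 1 to 3 lower when 1 array was left out, the highest without knockout replicate 2. The lists gained in these settings were epithelial-mesenchymal transition, chemokines and cytokines, adipocyte markers (all higher), unfolded protein response and basal genes (lower). The adipocyte list passed only without the dimmest 50% of genes. Its median was then 0.92, equal to the log2 fold change of Fabp4, against 0.02 with all genes. The cholesterol list had adjusted p = 0.0034, lost its call with an estimated correlation (0.549) and with fry (0.0922), and had adjusted p from 0.00034 to 0.032 elsewhere, 0.0028 to 0.032 with 1 array left out. Lists that were not past the threshold turned direction 21 times, always with no call. The adjusted p was then 0.996 for p53 targets (fry); for stem-cell-associated genes 0.987 (replicate block), 0.990 (quantile), 0.871 (dimmest 50% left out) and 0.821 (trend, and robust with trend); for S phase genes 0.987 (replicate block), 0.983 (median centring), 0.896 (mean of probe sets) and 0.998 (array weights); and without the dimmest 50% of genes 0.871 for milk protein and ErbB genes and 0.963 for endothelial markers. With 1 array left out, the adjusted p ran from 0.736 to 0.995 for S phase, 0.496 to 0.994 for milk protein, 0.503 to 0.995 for Ste20-family and 0.503 to 0.994 for glycolysis genes, which turned there. How far signal stood over background was not analysed here.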

Other observations

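The calls in the comparison of SLK-knockout with wild-type cells also included genes outside the fixed lists. Those of this and the next paragraph were picked one by one after their values were seen, and no test of them as groups was made. Apart from Eya4, how each fared with 1 array left out is not given here. Genes that rose were Timp3, an inhibitor of metalloproteases (log2 0.90, adjusted p = 0.0072), the secreted protein gene Srpx2 (0.77), and the collagen genes Col18a1 (0.69) and Col4a1 (0.41, adjusted p = 0.029). The family of 44 genes named Col did not pass as a whole (camera adjusted p = 0.31), with 29 having a higher mean in knockout cells. Further genes that rose were Ptprn, a protein of secretory granules (2.20-fold), the adhesion molecule L1cam (2.10-fold), the sodium channel gene Scn9a (2.02-fold), the ion channel gene Trpa1 (1.82-fold) and Nptx1 (1.68-fold), while the glutamate receptor gene Grik2 fell by 0.54 log2 units. Trpa1 was dim, at 2.72 in wild-type and 3.58 in knockout cells, against 4.38 for the median gene in wild-type cells.

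Among the genes that fell were the guidance ligand Slit2 (log2 -0.51, adjusted p = 0.022) and its receptor Robo1 (-0.53, adjusted p = 0.031), and Bmp4 (-0.53) together with Chrdl1, a secreted BMP antagonist (-0.52). Eya2 rose (0.64, adjusted p = 0.029) where its relative Eya4 fell (-1.19). Single glycosyltransferase genes also changed: St8sia6 (0.79) and St3gal1 (0.46), which add sialic acid, B4galt6 (1.03) and B3gnt3 (0.61) rose, and Galnt3, which starts mucin-type O-glycans, fell (-0.47, adjusted p = 0.049). Other single genes that rose were Hhip, an antagonist of hedgehog ligands (2.14-fold), Cd34 (1.92-fold), Egln3, a prolyl hydroxylase (1.82-fold), and the lipocalin Lcn2 (1.64-fold). Hhip was dim in wild-type and knockout cells (3.14 and 4.24), and B4galt6 was dim in wild-type cells (3.37). Mcpt8, a mast cell protease by name only and not on the leukocyte list, rose 2.24-fold (adjusted p = 0.0021). Its signal was already bright in wild-type cells (7.47 against 8.64 in knockout cells).

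Of the 10 ways to split the 6 arrays into 3 and 3, only 1, the real one, called as many genes (97), and the highest other count was 0, but 10 splits are too few for a share under 0.05. For 0% of the 97 genes did the median of the 25 neighbouring genes on each side shift in the same direction by at least 0.5 times as much, and, in a test chosen afterwards, 0 of 97 had the 2 nearest bright genes on each side follow by 0.5 times the gene's change or 0.5 times a full change of 1 copy, whichever was less. This argues against gains or losses of a full copy in all cells that take in most of these neighbours, if the cells otherwise hold 2 copies. The copy number of these cells is not given in the sources used here. Changes in part of the cells, or of 1 copy in cells with more than 2, would shift neighbours by less and stay open. So do changes confined to the gene itself or to fewer neighbours. Of the calls other than Slk, 0% lay among the 84 measured genes with bright signal closest to Slk, although 3 of these other calls are on its chromosome. A separate origin of the cultures of each genotype could account for any of the calls and cannot be told apart from loss of SLK, because 0 samples have a label that names a line, clone, animal or passage.

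Sox10 is a marker of Schwann cells as well as of mammary progenitors, so a few Schwann cells in the knockout cultures were considered. Of the other markers on that list, 7 were dimmer in wild-type cells than Sox10 was in knockout cells, and if such cells were the source, they should have gone up by at least 0.73 log2 units where Sox10 went up by 1.47. Their median log2 fold change was -0.083 (SD 0.24, n = 7 genes). However, 5 of the 7 were dimmer in wild-type cells than the median gene (4.38), where fold changes are compressed, so the test decides nothing and this source stays open. The test was written after the Sox10 value was seen.

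Median log2 fold changes of whole chromosomes were compared too, a question raised only after the gene values were seen. Among 11024 genes brighter than the median gene, placed on chromosomes with GRCm38.p6, 7 of 20 chromosomes had a median log2 fold change outside all 10000 shuffles matched on brightness, and 7 of 7 stayed outside without the zinc-finger genes named Zfp. The shuffles treat genes as independent, so they do not measure the spread between arrays or cultures. The medians were 0.07 for chromosome 18 (80.1% of genes above 0), 0.06 for 15, 0.05 for 12 and 0.01 for 2, and -0.05 for 7 (27.5% above 0), -0.05 for 14 and -0.03 for 13. The arrays of the 2 genotypes were fully apart on 6 of the 7, all but chromosome 2. These chromosomes were picked by the difference between the same arrays, so such separation was partly given in advance. A bias of probes could not be excluded, since the dimmer genes followed on 42.86% (3 of 7), though on 0 of 7 once the general offset of dim genes (0.02) and of bright genes (-0.01) was removed. With each of these chromosomes cut into 5 parts, 97.14% of the parts (34 of 35) had the sign of the whole, but so did 87.7% (57 of 65) on the other 13 chromosomes, so this share decides nothing about a gain or loss of whole chromosomes in part of the cells, which stays open.

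Of the 97 calls, 40 (41.2%) lie on these 7 chromosomes, which hold 34.4% of all genes placed, and the difference was not tested. The cholesterol synthesis list, with a median of -0.07, lay at percentile 0.79 of 10000 lists matched on mean value, and its adjusted p was 0.549 with an estimated correlation. The families named Snora (26 genes, median -0.16) and Zfp (370 genes, median -0.05) passed camera at its preset correlation beside Snord, and none of the 264 families passed with an estimated one. Of 17824 probe sets with no symbol or several, none was past the threshold when adjusted among themselves. In the fit adjusted over all 41345 probe sets 3 of them were, all higher in knockout cells: 17224771, which has no symbol (log2 1.10, adjusted p = 0.016), and 17530243 and 17375503, which have several (1.44 and 0.68, adjusted p = 0.025 and 0.046).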
